A study of Homo sapiens with 12 samples.

How the data were processed

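The study treated 22Rv1 cells for 6 h with vehicle, enzalutamide (1 µM), OSU-ERb-12 (100 nM) or both, with 3 samples per group, described as biological replicates per the labels' protocols. The samples of the combined treatment carry no doses in their own labels. The nucleosome-free fraction was separated with ATACSeqQC per the labels' protocols, and FastQC, Trimmomatic and the hg38 build are named per the submitters' processing notes. The peak caller, its threshold, the test against vehicle, the pooling of replicates, the handling of the transposase offset and the sign of the listed differences are not given in the sources used here. The names of the lists carry a short tag that could stand for a direction, but no source defines it, so no direction was assigned. Each list was matched to its treatment through the prefix it shares with the sample titles. For OSU-ERb-12 this prefix is WT, which the labels do not explain and also give as the genotype of all samples, so every OSU-ERb-12 value rests on that match.

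Each deposited list gives chromosome, start and end of a region, without a header. The deposited score column is 0 in every row, so no region could be ranked by strength. Region boundaries lie on a 50 bp grid, the shortest region is 200 bp, and neighbours are at least 300 bp apart; the median width is 250 bp for enzalutamide and 200 bp for the others. Regions of 200 bp make up 45.7% of the enzalutamide list, 66.1% of the OSU-ERb-12 list and 68.0% of the combination list. Sequencing depth and values per library are not in the lists, so results carry no replicate error, and intervals cover the counting of regions only. Samples treated with oestradiol, which the design text mentions, were not analysed here.

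Genes came from the RefSeq annotation of GRCh38.p14, the same build, with 20037 protein-coding genes on 24 chromosomes; coordinates are printed 1-based. This table gives no strand and no sequence was used. For this reason promoter windows, planned as 1 kb either side of gene starts, were replaced by windows of 1 kb either side of both ends of each protein-coding gene, transcript starts were not used, motif enrichment was not run, and assembly gaps were not left out of random placements. The extent of a chromosome was taken from its outermost gene or region.

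Regions of different lists were shared if they overlapped by at least 1 bp. Overlaps were compared with 1000 random placements of the shorter list that kept chromosome and width (one-sided permutation p), and gene-end shares with 1000 placements (two-sided). Association of overlaps, gene-end shares between lists and shares on chromosomes were tested with Fisher's exact test, two-sided, and densities per chromosome with exact binomial tests; shares have exact Clopper-Pearson 95% intervals, and odds ratios 95% intervals from 1000 bootstrap draws of 10 Mb blocks. A gene held a region if the gene body with 10 kb on either side overlapped it. Each of 19 gene lists was compared with 10000 random lists of protein-coding genes matched on decile of locus length (two-sided permutation p). Adjustment was by Benjamini-Hochberg over the 3 pairs, the 3 gene-end comparisons, all 57 list tests, the chromosomes and lists, or the 6 chromosome group tests, with a threshold of 0.05. The chromosome group tests were added after the densities were seen.

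Genes are named by a rule: for each treatment the 10 protein-coding genes with the smallest one-sided Poisson p for the number of regions in the locus, given locus length and the density of the list on the chromosome, without overlapping loci; in each gene list up to 4 members with the most regions; and ESR1, ESR2, FOXA1, HOXB13, KLK3, TMPRSS2, FKBP5 and MYC. The text prints the members that lead, and some genes that the rule takes are not reported here. CDK2 and IRF1 are named also because they were the 2 list genes whose locus held a combination region overlapping both other lists, which was counted after the data were seen. The gene lists, this rule, the main tests and the first set of other settings (another overlap rule, merging within 1 kb, other placements, autosomes alone, a 5 kb window, other locus windows, another gene background and covered base pairs) were fixed before the data were examined. Local placement, results without chromosomes 1, 3, 7, 8, 12 and X, and lists matched on chromosome group were added after the data were seen.

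The procedures were tested on simulated data. For the enzalutamide list, all of 100 simulated lists of 30 genes with 26 holding a region had p under 0.05 (100%), and 2% of 200 random lists did. Of 500 shared regions planted between simulated enzalutamide and combination lists, 501.7 were recovered above random overlap, and of 2000 planted gene-end regions 1990.5. A planted membership odds ratio of 8.41 was estimated as 7.54. Over 20 pairs of unrelated simulated lists the overlap was 0.97 times the random mean. These lists were themselves placed at random, so they do not show how far unrelated lists of accessible chromatin would overlap. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.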

Results

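Chromatin accessibility was profiled by ATAC-seq, which reads out the DNA that a transposase can reach, in 22Rv1, an established human prostate cancer cell line. There were 12 samples in 4 groups of 3: vehicle, enzalutamide at 1 µM, OSU-ERb-12 at 100 nM, and OSU-ERb-12 plus enzalutamide, each for 6 h. Enzalutamide is an antiandrogen drug used in prostate cancer, and OSU-ERb-12 is a ligand of oestrogen receptor beta. The analysed data were 3 deposited lists of genomic regions, 1 per treatment, with positions on the hg38 build and no value per library or per region. The enzalutamide list held 25317 regions that covered 6937.9 kb, the OSU-ERb-12 list 17931 regions (4111.8 kb) and the list for both agents, called the combination list here, 6248 regions (1421.8 kb). The lists were taken to come from a comparison with vehicle, which the sources used here do not describe. They also do not say whether the listed regions were more or less accessible than in vehicle. All results below are therefore about where the listed regions lie, and a gene without a listed region may still have changed. Sequencing depth per sample is unknown from the lists, and the length of each list depends on it.

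The enzalutamide list holds the regions listed for an antiandrogen. SLC2A1, the gene of the glucose transporter GLUT1 (chromosome 1, 42925353 to 42958868), held 15 enzalutamide regions in its locus, the gene body with 10 kb on either side, where 0.597 were expected from the locus length and the density of the list on the chromosome. The predicted gene LOC124905135 on chromosome 22 (46044644 to 46113928) held 18 regions against 0.743 expected, and BCOR, which encodes a corepressor of BCL6, held 11 against 0.597.

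Other loci that ranked highest for enzalutamide were LOC124902461 (8 regions, 0.234 expected), RAB40C (9, 0.543 expected), ALDH3A2, a fatty aldehyde dehydrogenase (9, 0.566 expected), TBX3, a T-box transcription factor (8, 0.402 expected), the histone demethylase KDM6B (8, 0.465 expected), JMJD8 (6, 0.205 expected) and PRRT2 (6, 0.215 expected). Among the classical androgen-regulated genes, KLK3, which encodes prostate-specific antigen, held 3 enzalutamide regions (0.411 expected), FKBP5 held 2 (1.32 expected), and TMPRSS2 held none. Of the lineage factors, FOXA1 held 2 (0.177 expected) and HOXB13 held 3 (0.275 expected). MYC held 3 (0.259 expected), ESR1 6 (3.71 expected) and ESR2, the gene of oestrogen receptor beta, 3 (0.911 expected). Expected numbers come from locus length and chromosome only, and regions cluster, so they rank genes and were not used as a test.

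**Figure D1:**
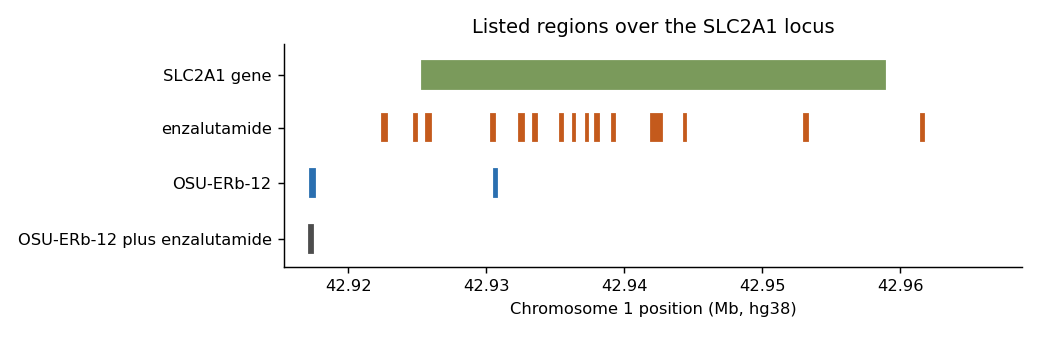
Position on chromosome 1 in Mb (hg38) across the SLC2A1 locus, with the gene as a green bar and each listed region of the 3 treatments as a block to scale. The locus held 15 enzalutamide regions, 2 OSU-ERb-12 regions and 1 combination region.

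The OSU-ERb-12 list holds the regions listed for a ligand of oestrogen receptor beta. Its highest-ranking loci were LOC124900940 (5 regions, 0.0992 expected), GATD1 (5, 0.172 expected) and KIAA0040 (7, 0.556 expected). The locus of PSMB4, a proteasome subunit gene (chromosome 1, 151399573 to 151401937), held 5 regions against 0.222 expected, none of which was shared with enzalutamide. EVC2, a gene of ciliary signalling, held 7 (0.597 expected), and the kinase gene LMTK2 held 9 (1.16 expected). CSRP1 (6, 0.433 expected), CPNE5 (6, 0.444 expected) and KREMEN2, a receptor for Wnt antagonists (4, 0.127 expected), also ranked among the highest. KIAA0040, PSMB4 and CSRP1 lie on chromosome 1 after position 143654150. There the list held 16.5 regions per Mb, against 9.92 on the whole chromosome, so the numbers expected for these genes are too low.

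Of the oestrogen receptor genes, ESR2 held 2 regions (0.495 expected), at 64220451 to 64220750 and 64304101 to 64304300 on chromosome 14, and ESR1 held none (1.84 expected). KLK3, FOXA1 and MYC held 1 each, while HOXB13, FKBP5 and TMPRSS2 held none. Between KLK3 and KLK2 the OSU-ERb-12 region at 50870001 to 50870350 on chromosome 19, 9411 bp outside KLK3 and 3264 bp outside KLK2, overlapped the enzalutamide region at 50870301 to 50870550.

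The combination list holds the regions listed for both agents together. FAM53A on chromosome 4 (1574062 to 1686017) held 6 combination regions against 0.146 expected; 1 of them was also an OSU-ERb-12 region and none overlapped an enzalutamide region. The locus of DGKA, a diacylglycerol kinase gene, held 4 (0.169 expected), MIDEAS 4 (0.139 expected) and GRIP2 5 (0.399 expected). The other high-ranking loci held 3 regions each, namely CTDSP1 (0.0426 expected), the DNA polymerase gene POLL (0.0560 expected), LOC124900163 (0.0597 expected), RAB26 (0.0623 expected) and SKP1, a subunit gene of ubiquitin ligases (0.0712 expected), apart from PQBP1 with 2 (0.00986 expected). FOXA1, HOXB13, MYC and ESR1 each held 1 combination region, and ESR2, KLK3, TMPRSS2 and FKBP5 held none.

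Several combination regions at these genes were also enzalutamide regions. In MYC the region at 127735751 to 127735950 on chromosome 8, inside the gene, had the same boundaries in both lists. At FOXA1 the combination region at 37588751 to 37588950 on chromosome 14 lay within the enzalutamide region at 37588651 to 37588950, and at HOXB13 the region at 48720901 to 48721100 on chromosome 17 lay within the one at 48720901 to 48721350. Of 386 genes in the fixed lists other than olfactory receptors, 2 had in their locus a combination region that overlapped regions of both other lists, as did 283 of all 20037 protein-coding genes. For CDK2, the cell cycle kinase gene, it lay at 55957201 to 55957400 on chromosome 12, 9530 bp outside CDK2 and nearer to DGKA, 3277 bp away. For IRF1, an interferon regulatory factor gene, the combination region spanned 132473701 to 132473900 on chromosome 5, 7809 bp outside the gene.

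Across the genome, 4698 of the 6248 combination regions (75.2%; exact 95% interval 74.1 to 76.3) overlapped neither single-agent list by 1 bp or more. A further 756 (12.1%) overlapped an enzalutamide region alone, 533 (8.53%) an OSU-ERb-12 region alone and 261 (4.18%) both. Combination regions shared with enzalutamide were also more often shared with OSU-ERb-12: 25.7% of 1017 against 10.2% of the other 5231, an odds ratio of 3.04 (block bootstrap 95% interval 2.53 to 3.62; Fisher's exact test, two-sided p = 9.45e-36). Regions are not replicates, so this p describes these lists only.

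**Figure D2:**
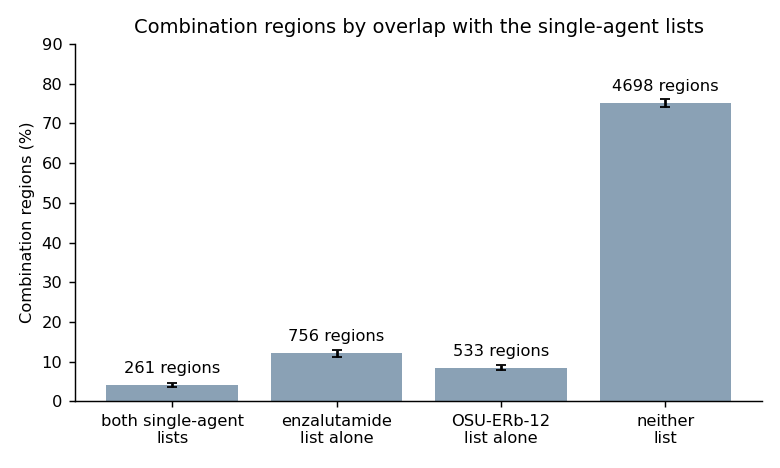
Percent of the 6248 combination regions (vertical axis) by overlap with the single-agent lists (bars), with exact 95% binomial intervals as error bars and the number of regions above each bar. The bar for neither list reaches 75.2%, against 12.1% for the enzalutamide list alone and 8.53% for the OSU-ERb-12 list alone.

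The single-agent lists shared few regions. Of the 17931 OSU-ERb-12 regions, 1564 (8.72%; interval 8.31 to 9.14) overlapped an enzalutamide region, against a mean of 83.8 under random placement on the same chromosomes, a ratio of 18.7. Of the combination regions, 1017 (16.3%; 15.4 to 17.2) overlapped an enzalutamide region and 794 (12.7%; 11.9 to 13.6) an OSU-ERb-12 region, ratios of 35.2 and 38.7 to random placement. In each pair no placement of 1000 reached the observed overlap (one-sided permutation p = 0.001, the smallest that the placements can give; adjusted p = 0.001). The lists come from the same cell line, and the placements could fall on DNA that is not accessible. Overlap above random placement therefore does not separate the treatments from accessible chromatin that the lists have in common. The ratios depend on the comparison: with regions moved by up to 100 kb they were 12.3, 19.9 and 22.6, with placements that kept gene-end regions at gene ends 13.3, 17.9 and 31.5, with neighbours within 500 bp counted as shared 7.48, 13.9 and 13.6, and with at least 50% of the shorter region required 30.4, 58.4 and 68.0. The study has a single vehicle group, so part of the overlap may come from shared vehicle libraries, and lists without values per library do not allow that part to be measured.

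At the level of genes, 11680 of 20037 protein-coding genes (58.3%) held an enzalutamide region in their locus, 7844 (39.1%) an OSU-ERb-12 region and 4353 (21.7%) a combination region. All 3 lists had a region at 2213 genes, where 1357.8 would be expected if the lists were independent among genes of like locus length. That expectation does not allow for accessibility or chromosome. The excess therefore does not separate the treatments from accessible chromatin that the lists have in common. A total of 5876 genes held none.

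Enzalutamide regions gathered at the ends of protein-coding genes, and OSU-ERb-12 regions far less so. Within 1 kb of either gene end lay 22.4% of enzalutamide regions (exact 95% interval 21.9 to 22.9), 15.6% of combination regions (14.7 to 16.5) and 8.09% of OSU-ERb-12 regions (7.70 to 8.50). Random placement gave 2.96%, 2.97% and 2.88%, so the shares were 7.58, 5.24 and 2.81 times those of random placement (two-sided permutation p = 0.002 for each, the smallest that the placements can give). The placements covered whole chromosomes, including DNA that the transposase cannot reach. These ratios therefore do not set the listed regions apart from accessible chromatin as a whole. At ENO2, SYP and RPLP1, for example, 3, 2 and 3 enzalutamide regions lay at a gene end. Bodies of protein-coding genes away from their ends held 38.8% of enzalutamide, 46.3% of OSU-ERb-12 and 43.6% of combination regions, and 27.8%, 32.7% and 29.4% lay in no annotated gene.

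**Figure D3:**
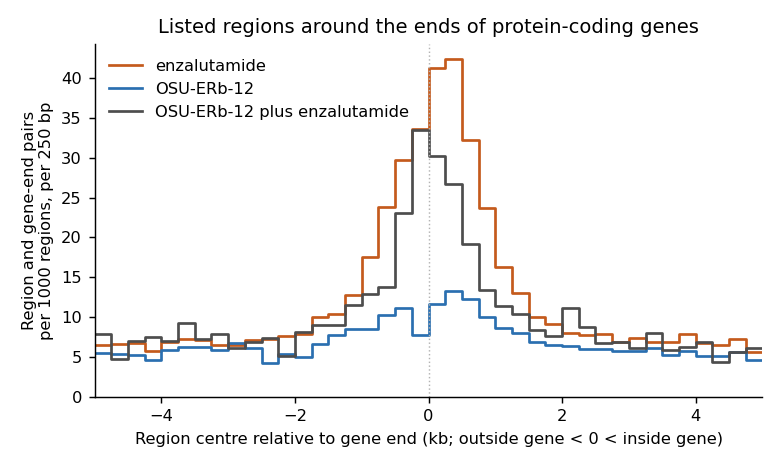
Pairs of a region and a protein-coding gene end per 1000 regions (vertical axis) in bins of 250 bp by the distance of the region centre from the gene end in kb (horizontal axis; negative values lie outside the gene), 1 line per list. The enzalutamide line peaks at 42.4 in the bin that starts 250 bp inside the gene, and the OSU-ERb-12 line stays below both others within 500 bp of the gene end.

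The difference between the single agents was also tested on regions found in only 1 of their lists, which is not an independent check. The whole lists had 22.4% for enzalutamide and 8.09% for OSU-ERb-12, so leaving out shared regions lowered the OSU-ERb-12 share more. Of the 23755 enzalutamide regions that overlapped no OSU-ERb-12 region, 22.0% lay at a gene end, against 6.21% of the 16367 OSU-ERb-12 regions that overlapped no enzalutamide region, an odds ratio of 4.26 (block bootstrap 95% interval 3.996 to 4.59). Combination regions shared with enzalutamide lay at gene ends in 38.2% of cases and those in neither list in 11.0% (odds ratio 4.99, 4.31 to 5.81; Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 1.44e-85). For combination regions shared with OSU-ERb-12 the share was 21.3% (odds ratio 2.19, 1.83 to 2.62; Fisher's exact test, adjusted p = 3.44e-14). Of the 261 combination regions that overlapped both other lists, 101 (38.7%, exact interval 32.8 to 44.9) lay at a gene end. Both single-agent lists were themselves rich at gene ends, so overlap with either picks out gene-end regions. A higher share than among combination regions in neither list would follow from the overlap alone. These comparisons therefore describe the lists and do not test a further link. With a window of 5 kb the odds ratio between the single agents was 2.35, and the ratios to random placement were 3.12 for enzalutamide, 1.83 for OSU-ERb-12 and 2.52 for the combination. The annotation used here gives no strand, so starts and ends of genes were counted together.

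Androgen response genes were widely covered in the enzalutamide list, as were some other lists, and they did not pass the adjusted test. Coverage was 82.5%, within a range from 11.7% for olfactory receptors to 87.0% for p53 pathway and apoptosis genes. An enzalutamide region was present at 33 of the 40 androgen response genes, where random lists of the same locus lengths held 26.1 on average (permutation p = 0.021, adjusted p = 0.176). The ratio to random was 1.27, and 1.13 against genes that held a region of any list (permutation test, adjusted p = 0.847). ELL2, an elongation factor gene, and TPD52 held 6 regions each, and KLK2 and SPDEF, a prostate ETS factor gene, held 4 each. In the OSU-ERb-12 list 20 of the 40 genes held a region (18.3 at random), led by PLPP1 with 3, and in the combination list 9 (10.1 at random), led by MAF with 2. Of the p53 pathway and apoptosis genes, 20 of 23 held an enzalutamide region (13.2 at random, permutation p = 0.0048, adjusted p = 0.068 over all 57 tests). BBC3, MCL1 and PLK3 held 3 each and CDKN1A held 2. Over the 19 enzalutamide tests alone the adjusted p was 0.046, but the adjustment used for the gene lists covers all 57. These genes also did not pass under any alternative setting, including 1 kb either side of gene ends. The adjusted p of the permutation test was 0.347 with 50 kb either side. It was 0.847 against genes that held a region of any list, and 0.12 with matching on chromosome group. The same list gave 11 genes for OSU-ERb-12 and 8 for the combination.

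Ribosomal protein genes held enzalutamide regions at 21 of 31 members (14.0 at random, permutation p = 0.017, adjusted p = 0.176), among them RPLP1 with 5 regions and RPS2 with 4. When only the 1 kb on either side of gene ends was counted, 18 of the 31 genes held an enzalutamide region, 2.37 times the random share, and the list passed the adjusted threshold (permutation test, adjusted p = 0.0057; 0.0057 to 1 over the alternatives). OSU-ERb-12 regions lay at 9 and combination regions at 5 of the ribosomal genes, against 8.16 and 4.81 at random.

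Nuclear receptor and coregulator genes were the list with the lowest p above chance for OSU-ERb-12, with 30 of 41 genes holding a region (22.7 at random, permutation p = 0.022, adjusted p = 0.176). RARB held 12 and THRB 8 on chromosome 3, and ESRRG held 7 and NR5A2 4 on chromosome 1, both of them chromosomes on which this list was dense. For RARB 8.64 and for ESRRG 6.49 were expected at the mean density of the chromosome. On chromosome 1 this list held 6.05 regions per Mb before position 121586850 and 16.5 after position 143654150. For a locus in the denser part, a number expected from the mean is therefore too low. For the gene list as a whole, the OSU-ERb-12 ratio to random lists was 1.32 in the main test. With random lists matched also on chromosome group it was 1.29 (permutation test, adjusted p = 0.239). For enzalutamide 34 of the 41 genes held a region (30.03 at random), with 16 at ESRRG and 7 at the coactivator gene NCOA2, and for the combination 17 (12.7 at random), with 3 at PPARD. Oestrogen response genes numbered 17, 14 and 9 of 24 with a region for enzalutamide, OSU-ERb-12 and the combination, against 14.7, 9.93 and 5.43 at random. The cyclin D gene CCND1 held 4 enzalutamide and 2 OSU-ERb-12 regions, and CA12 held 3 OSU-ERb-12 regions.

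Prostate lineage factors with a region numbered 15, 11 and 5 of 18 in the same order of treatments, with 5 enzalutamide regions each at EHF, GATA3 and GRHL2. For luminal epithelial markers the numbers were 10, 6 and 1 of 14, where KRT8 held 7 enzalutamide and 4 OSU-ERb-12 regions, and for basal markers 9, 8 and 1 of 14, where EGFR held 8 and 5. Neuroendocrine markers gave 12, 10 and 3 of 18, with 5 enzalutamide regions at the neural factor POU3F2 and 5 OSU-ERb-12 regions at NCAM1. Glucocorticoid response genes gave 13, 6 and 1 of 16, led in each list by ZBTB16 with 8, 4 and 2 regions. Cell cycle genes gave 18, 10 and 10 of 30, Wnt genes 13, 12 and 7 of 20, epithelial-mesenchymal transition genes 15, 10 and 3 of 20, interferon genes 12, 8 and 4 of 21, and NF-kB genes 7, 7 and 3 of 18. None of these passed the test.

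Markers of cells that a pure culture of this line would lack did not pass the test in any list. Leukocyte markers held a region at 7, 7 and 2 of 18 genes for enzalutamide, OSU-ERb-12 and the combination, fibroblast and endothelial markers at 8, 9 and 3 of 15, and hepatocyte markers at 7, 5 and 1 of 18. Olfactory receptor genes, silent in most tissues, were the only list past the threshold when adjusted over all tests. A region was present at 46 of 392 for enzalutamide (160.5 at random), 35 for OSU-ERb-12 (93.6) and 4 for the combination (55.4), each with permutation p = 0.0002, the smallest that 10000 random lists can give, and adjusted p = 0.0038. Against genes that held a region of any list, this depletion no longer passed for enzalutamide and OSU-ERb-12. In all, 57 tests of 19 lists were made, 7 had an unadjusted p under 0.05, and 3 passed after adjustment.

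**Figure D4:**
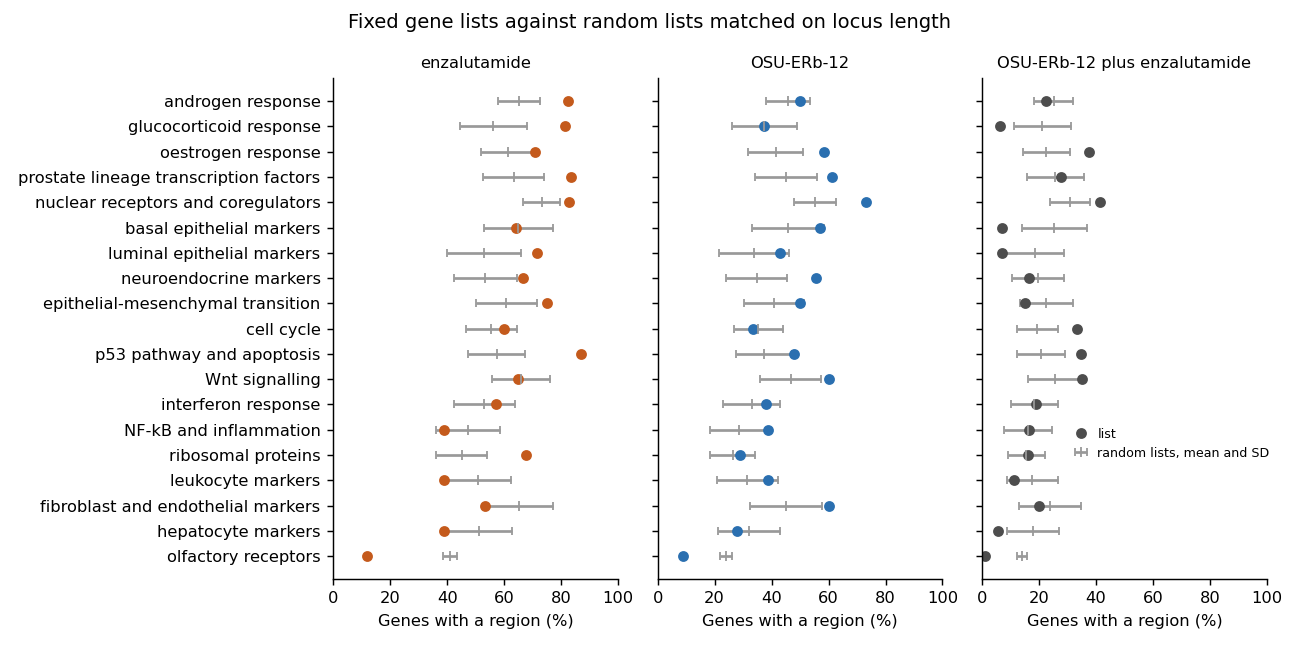
Percent of the genes of each fixed list (rows) that held a listed region in the gene body with 10 kb on either side, as coloured points, beside the mean and SD of 10000 random lists matched on locus length in grey, 1 panel per treatment. Olfactory receptors lie below their random lists in each panel (11.7%, 8.93% and 1.02%).

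OSU-ERb-12 regions crowded on chromosomes 1, 3, 7, 8 and 12, which held 50.0% of that list, 44.5% of the combination list and 37.1% of the enzalutamide list. Chromosome 3 held 2171 OSU-ERb-12 regions, 1.89 times the density of the list as a whole (exact 95% interval 1.81 to 1.96), and chromosome 12 held 1413, 1.83 times (1.74 to 1.92). Relative densities were 1.71 on chromosome 1, 1.63 on chromosome 7 and 1.66 on chromosome 8. On chromosome X the list was thin, with 107 regions at a relative density of 0.118 (0.0969 to 0.143), against 637 enzalutamide regions at 0.498 (0.461 to 0.538).

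Over chromosomes 3, 7, 8 and 12 together, OSU-ERb-12 regions were 2.29 times as dense as over the other autosomes without chromosome 1 (block bootstrap 95% interval 1.70 to 3.00), combination regions 1.81 times (1.31 to 2.42) and enzalutamide regions 1.36 times (1.02 to 1.81). On chromosome 1 the density differed between the sides of the longest stretch without an enzalutamide region, from 121586850 to 143654150: after it, OSU-ERb-12 regions were 2.72 times as dense as before it, combination regions 1.99 times and enzalutamide regions 1.61 times. Chromosome 19, rich in genes, was dense in all 3 lists (1.94, 1.64 and 2.09 times for enzalutamide, OSU-ERb-12 and the combination). An OSU-ERb-12 region lay on chromosomes 1, 3, 7, 8 and 12 with an odds ratio of 1.69 to an enzalutamide region (block bootstrap 95% interval 1.60 to 1.80; Fisher's exact test with Benjamini-Hochberg adjustment over 6 tests, adjusted p = 6.06e-155), and on chromosome X with an odds ratio of 0.233 (0.198 to 0.279; adjusted p = 4.35e-58). These chromosomes were grouped after their densities had been seen.

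**Figure D5:**
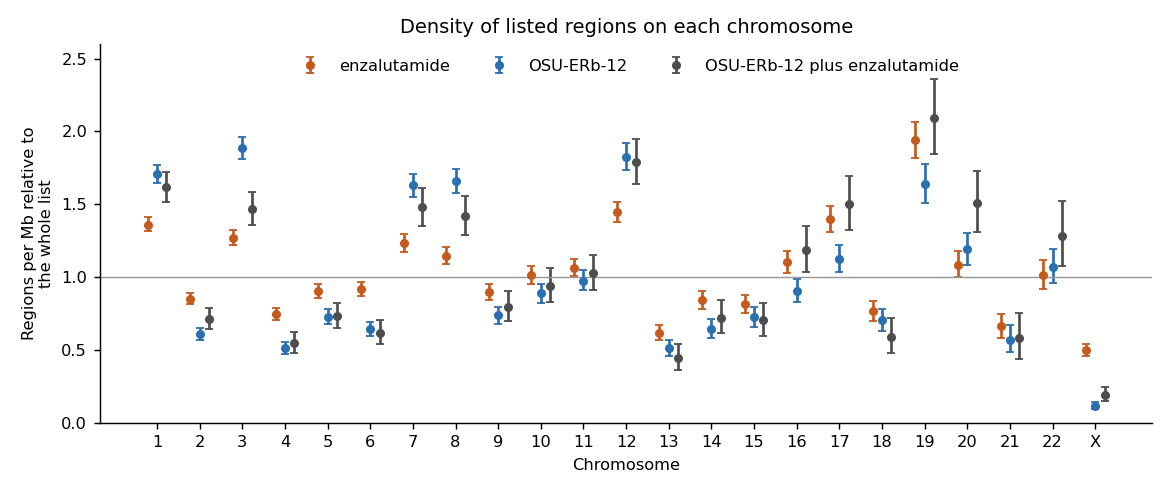
Listed regions per Mb on each chromosome relative to the whole list (vertical axis) for chromosomes 1 to 22 and X (horizontal axis), with exact 95% binomial intervals, 1 colour per list. OSU-ERb-12 points lie above the enzalutamide points on chromosomes 1, 3, 7, 8 and 12 and below them on X (0.118 against 0.498).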

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

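The chromosome groups, the tests on gene number, on 10 Mb bins and without chromosomes 1, 3, 7, 8, 12 and X, and the comparison of gene-end with other regions on the crowded chromosomes were chosen after the crowding had been seen.

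OSU-ERb-12 regions differed from enzalutamide regions in where they lay: the odds ratio of a place on chromosomes 1, 3, 7, 8 and 12 was 1.69 (1.60 to 1.80), and of a place on chromosome X 0.233 (0.198 to 0.279). Gene number as the whole cause is argued against, since chromosomes 3, 7, 8 and 12 held 2.61 times as many OSU-ERb-12 regions per protein-coding gene as the other autosomes without chromosome 1 (95% interval 1.94 to 3.41). A factor spread over whole chromosomes or arms, such as copy number, stays open. Bins of 10 Mb were taken on chromosomes 3, 7, 8 and 12 and on chromosome 1 after its long stretch without an enzalutamide region. Of these, 76 of 76 (100%) held more OSU-ERb-12 regions per enzalutamide region than the median bin of the other autosomes. However, these chromosomes were picked for their density. The same was true of 7 of 7 bins on chromosome 20, 5 of 5 on chromosome 22 and 7 of 12 on chromosome 1 before that stretch. A detection threshold that extra copies help to pass cannot be told apart from other causes by region width. The excess among 200 bp regions was 0.945 times that among wider ones (0.884 to 1.02). On chromosomes 3, 7, 8 and 12 the OSU-ERb-12 excess per Mb was 2.42-fold away from gene ends and 1.19-fold at them. This split was not particular to OSU-ERb-12, with 1.53-fold against 0.865-fold for enzalutamide and 1.97-fold against 1.06-fold for the combination. Counts were set against Mb and not against gene ends. The OSU-ERb-12 ratio was 2.61 per gene and 2.29 per Mb, so fewer genes per Mb on these chromosomes lower the gene-end values. Copy number of these cells was not measured here, and an effect of the ligand on particular chromosomes was not tested. All groups came from the same cell line, so copy number alone gives neither a difference from vehicle nor a difference between lists. That part of the OSU-ERb-12 list follows DNA dosage, through how easily regions are called, remains a candidate explanation that was not tested.

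Enzalutamide regions also differed from OSU-ERb-12 regions in lying at gene ends, with an odds ratio of 4.26 (3.996 to 4.59) between regions found in only 1 of these lists. Leaving out shared regions widens this contrast. The shares at gene ends were 22.4% and 8.09% in the whole lists, and 22.0% and 6.21% without shared regions. Region width does not account for the difference, as the odds ratio was 3.93 (3.61 to 4.31) among regions of 200 bp. The chromosomes on which the OSU-ERb-12 list crowds do not account for it either, as it was 3.90 (3.603 to 4.26) without chromosomes 1, 3, 7, 8, 12 and X. What stays open is the authors' threshold or depth, which no value in the lists tests, and a different reach of the ligands, so a biological difference is a hypothesis that was not tested.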

How the results depend on the processing

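The setting without chromosomes 1, 3, 7, 8, 12 and X, local placement and matching on chromosome group were chosen after the data were seen. Of 101 comparisons of main results with an alternative, 82 kept direction and side of the threshold or stayed within their interval, among them all 18 chromosome densities in covered base pairs; the overlap ratios, the membership odds ratio and the gene-end odds ratios passed under every alternative run. For the others the cause was not tested beyond what each setting changes by construction. The shared percent of enzalutamide and OSU-ERb-12 was 8.23 with an overlap of at least 50% of the shorter region; within 500 bp the percents of the 3 pairs were 10.3, 19.1 and 14.2, and without chromosomes 1, 3, 7, 8, 12 and X 10.1, 18.7 and 11.9. The percent of combination regions in neither list was 79.4 outside gene ends and 74.1 without those chromosomes. Gene-end percents for enzalutamide, OSU-ERb-12 and the combination were 35.0, 20.4 and 29.0 with a 5 kb window and 25.2, 10.3 and 18.0 without those chromosomes, and 21.5 for enzalutamide with regions within 1 kb merged. For enzalutamide, 2 gene lists passed with 1 kb either side of gene ends, and with genes holding a region of any list as background 0 passed for enzalutamide (1 at an unadjusted p under 0.05) and 0 for OSU-ERb-12 (0 unadjusted), where 1 each had passed. Against that background olfactory receptors turned from below to 1.06 times random for OSU-ERb-12 and reached 0.845 times for enzalutamide. No paired analysis was possible because the lists hold no values per library; leaving out replicates, a stricter threshold, transcript starts and motifs were not run for want of such values, strand or sequence. Depth is unknown and limits what each list can hold.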

Other observations

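The test of independent draws was chosen after the overlaps had been seen.

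Most combination regions, 75.2%, lay in neither single-agent list, FAM53A with 5 such regions among its 6 being an example. Slightly shifted boundaries as the cause are argued against, since 71.7% (70.5 to 72.8) still had no single-agent region within 500 bp. Independent draws from a single set of equally likely accessible regions would need a like set size for each pair. The largest was 2.06 times the smallest (1.82 to 2.32). Set sizes were 290255 for the single agents, 155536 for enzalutamide and the combination and 141099 for OSU-ERb-12 and the combination. Where some accessible regions are called more easily than others, set sizes can differ between pairs. The test therefore cannot decide on draws from such a set, which stay open. Calls near the detection limit stay open as a candidate explanation. Combination regions of 300 bp or more lay in a single-agent list 1.80 times as often as those of 200 bp (1.61 to 1.98), 38.0% of 895 against 21.1% of 4249. However, a wider region also meets an overlap of 1 bp more easily, and this was not allowed for. The ratio therefore cannot decide whether calls lay near the limit. An effect of the combined agents that neither has alone also stays open and was not tested.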
